A study of Mus musculus and Homo sapiens with 34 samples.

How the data were processed

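PolyA RNA was sequenced from spheroids of 3 colorectal carcinoma lines, as 22 mouse libraries (CT26 and MC38) and 12 human libraries (HT29). Per the labels' protocols, cells were seeded in ultra-low attachment U-bottom plates with or without decellularised SIS ECM, spheroids were collected after 7 days in groups of 10 per tube, and RNA was purified with TRIzol and the RNeasy Micro kit. Libraries were made with a stranded mRNA kit, pooled within each species and sequenced as read pairs on a NovaSeq instrument, per the labels. The labels name cutadapt 1.18, STAR 2.7.0f, RSEM 1.3.1 and limma and the builds mm10 and hg38 in the submitters' processing notes, without saying which step each was used for. The strand setting of the counting is not given in the sources used here.

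The authors deposited 1 table of expected counts per gene for each species, with Ensembl identifiers and symbols and 55450 mouse and 58870 human genes. These estimated counts, as deposited, were not normalised: library totals ran from 15.8 to 24.2 (in 1e6 counts) in mouse and from 25.5 to 37.0 in human. Between 2244 and 2621 values per mouse library and between 3811 and 4113 per human library were not whole numbers, so all values were rounded before any count test. The authors also deposited, per the file headers, a log2 fold change, a t statistic (a score) and raw and adjusted p-values per gene for SIS ECM against cells alone in each line, and a normalised enrichment score with a p-value for each Hallmark gene set, from genes ranked by that t statistic. Values from these tables are given as the authors', and 34 per-sample columns in them were not used. All 55450 mouse identifiers matched the GENCODE annotation of the mm10 build, from which mouse coordinates were taken. Human coordinates were not used here.

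Replicate numbers were those in the labels. MC38 was represented by cells-alone libraries 1 to 5 and SIS ECM libraries 1, 3, 4, 5 and 6. The labels do not say whether libraries of one group came from separate cultures or days, so p-values measure the spread between these libraries, which may be technical. No library repeated another: in 80 pairs of libraries from one group, the chi-square per degree of freedom over genes with at least 20 counts ran from 1.89 to 137, and no pair held identical values.

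Genes changed by SIS ECM were tested in each line separately with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F test, two-sided, with TMM factors (0.917 to 1.08 in mouse, 0.972 to 1.03 in human) and the filterByExpr rule with a minimum count of 10. All adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested in that fit, and genes below 0.05 are described as having risen or fallen. CPM values are scaled by TMM factors, given as mean ± SD over libraries, and log2 fold changes are given ± SE. The difference between MC38 and CT26 in their response to SIS ECM was tested as an interaction over all mouse libraries. The response in HT29 was tested against the mean response of both mouse lines over 16667 genes whose symbols match between species when case is ignored, which stand in for orthologs. Genes changed in one direction in all lines were counted beside the number that independent lists give, and pairs of lines were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment.

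A set of 25 gene lists was fixed before the data were examined, together with the tests, the alternatives, the sample groups and the rule for naming genes. The lists hold interferon-stimulated genes, MHC class I presentation genes, collagens and matrix glycoproteins, integrins and matrix receptors, matrix proteases with inhibitors and crosslinkers, mesenchymal genes, epithelial junction genes, intestinal differentiation genes, stem cell and Wnt target genes, hypoxia genes, glycolysis genes, cholesterol synthesis genes, fatty acid genes, cell cycle genes, p53 target genes, NF-kB and inflammatory genes, unfolded protein response and ATF4 genes, immediate early genes, TGF-beta and YAP target genes, NRF2 and oxidative stress genes, mitochondrially encoded genes, and markers of fibroblasts, smooth muscle, endothelium and leukocytes. Lists with at least 3 tested members were tested with camera in limma 3.58.1, at a preset correlation of 0.01 between genes and with Benjamini-Hochberg adjustment within a comparison, and again with a correlation estimated from the data. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median.

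Named genes were, per line, the 8 highest and 8 lowest log2 fold changes among genes below 0.05 with a mean log2 CPM of at least 2 and every SIS ECM library on one side of every cells-alone library, leaving out predicted and clone-named genes. To these were added up to 4 changed members of each list that passed camera and up to 2 members with the smallest adjusted p of each other list, the 8 genes per direction that changed most in all lines, and the 5 highest and 5 lowest differences between MC38 and CT26. The text gives a selection of these, chosen with their values in view, preferring calls that no left-out library ended. Some genes that these rules select are not reported here, though all counts include them. Other genes are named only where they make up a count of 5 or fewer, after their values were seen. Genes of families with near-identical copies (Prl2c2, Ces1f, Ifi204, SULT1A4, the APOBEC3 and AKR1B genes, MHC class I, Scd1 and Scd2) and the antisense gene SSTR5-AS1 share reads with other genes, so their values are uncertain.

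Replicate numbers recur across cultures, so a fit with the number as a block was planned. It used only libraries whose number occurs in both cultures of a line. MC38 cells-alone library 2 and SIS ECM library 6 were thus left out of it, also in comparisons between lines. Libraries of one number deviated from their group means together in both mouse lines, with correlations across genes of 0.222 to 0.484 over 6 pairs in CT26 and 0.189 to 0.321 over 4 pairs in MC38, and so counted as paired. Only 2 of 6 and 1 of 4 pairs correlated best with their own number, and after the difference between libraries 1 to 3 and libraries 4 to 6 was removed the correlations were −0.37 to 0.07 and −0.07 to −0.01. The pairing is thus a hint from the data, carried by these number ranges, and blocked values stand beside results they change. In HT29 the numbers did not pair the libraries.

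The other alternatives were RLE factors, library totals alone, no filter, a minimum count of 30, DESeq2 1.42.0, limma-voom, both mouse lines in one fit, a 2-fold minimum, leaving out each library in turn and, chosen after the data were seen, a term for the number ranges, each range alone, and HT29 without SIS ECM libraries 1 and 4. Principal components were computed over the 2000 most variable genes. Groups were also compared with other splits of the same libraries, up to 100 splits with the true one included. The gene and list tests were also run on counts simulated with the means and spread of the deposited counts, with 200 changed genes. Each gene had 1 mean over all libraries of a fit, apart from the changes put in. The simulated counts thus held no difference between number ranges, lines or species and no correlation between genes. The shares below do not cover data with such structure. At a 1.5-fold change edgeR recovered 61.2% of changed genes in CT26 (12155 genes run), 77.6% in MC38 (13038), 89.6% in HT29 (15071), 30.8% for the difference between MC38 and CT26 (13743) and 87.7% for HT29 against the mouse lines (11940). At a 2-fold change the shares were 97.0, 95.4, 95.5, 78.8 and 95.3%, and false calls made up 6.52, 3.78, 4.64, 3.65 and 7.07% of all calls.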

Results

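Culture with SIS ECM shifted expression in all 3 colorectal carcinoma lines. Interferon-stimulated genes rose in CT26 and HT29, cholesterol synthesis genes fell in MC38 and HT29, and collagen genes fell in MC38. With a correlation between genes estimated from the data, the lists in CT26 and MC38 no longer passed (adjusted p = 0.0524 for interferon-stimulated genes in CT26, 0.0655 for cholesterol synthesis genes and 0.143 for collagens in MC38). The first principal component separated the cultures in HT29 (21.5% of the variance) and the second did so in MC38 (19.7%). In CT26 neither of the first 2 components (37.6 and 25.1%) separated them alone. SIS ECM changed 1135 of 12269 genes in CT26 (9.25%; 755 higher, 380 lower), 1206 of 13146 in MC38 (9.17%; 502 higher, 704 lower) and 2058 of 15207 in HT29 (13.5%; 1178 higher, 880 lower). Most changes were modest, with a median absolute log2 fold change among changed genes of 0.51 in CT26, 0.40 in MC38 and 0.26 in HT29. A change of at least 2-fold was seen in 222, 77 and 53 of them. The excess of rising genes in CT26 depended on the fit. With a term for the number ranges 1859 rose and 1686 fell, in libraries 1 to 3 alone 1231 and 1253, and in libraries 4 to 6 alone 1369 and 964. At 2-fold or more 207 rose and 15 fell. In MC38 1608 rose and 1638 fell with the term.

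**Figure D1:**
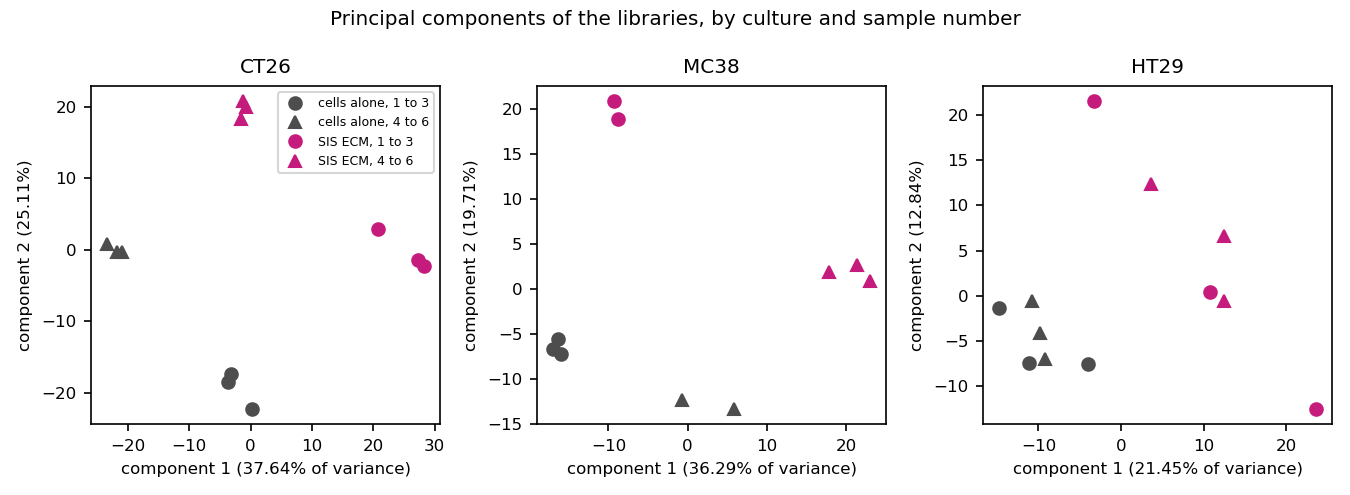
First 2 principal components of each line's libraries, by culture and replicate number range. Cultures separate on the first component in HT29 and on the second in MC38.

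The mouse libraries also differed by replicate number, with 6467 genes in CT26 (52.7%) and 5362 in MC38 (40.8%) differing between libraries 1 to 3 and libraries 4 to 6, against 0 in HT29. Transcripts encoded by mitochondrial DNA made up 4.42 ± 0.60% of counts in CT26 libraries 1 to 3 and 8.07 ± 0.36% in libraries 4 to 6, and 4.15 ± 0.72% and 6.28 ± 0.60% in MC38. Both cultures occur in both number ranges, equally in CT26 but not in MC38. There, libraries 1 to 3 hold more cells-alone libraries and libraries 4 to 6 more SIS ECM libraries. The main fit has no term for the ranges, so part of their difference can enter the SIS ECM effects in MC38. Some MC38 medians over all libraries lie beyond those of both ranges, such as cholesterol synthesis genes (−0.38 against −0.30 and −0.35). With such a term all 1206 MC38 calls still passed. Across all genes the log2 fold changes with SIS ECM in libraries 1 to 3 correlated with those in libraries 4 to 6 at 0.634 in CT26 and 0.324 in MC38. Median changes of gene lists in the mouse lines are given below over all libraries, followed in brackets by libraries 1 to 3 and libraries 4 to 6.

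In CT26, SIS ECM raised interferon-stimulated genes, 22 of 25, together with secreted matrix proteases. Neither list passed with an estimated correlation (adjusted p = 0.0524 and 0.210). The largest rise among the genes named was in the collagenase gene Mmp13, and the stromelysin genes Mmp3 (log2 fold change 2.22) and Mmp10 (2.21) came next among the proteases named. Genes of antiviral defence rose, among them the interferon regulator Irf7 (2.09), the interferon-induced deISGylase Usp18 (1.86), the antiviral GTPase Mx1 (1.85) and the oligoadenylate synthetase Oas2 (1.68). Machinery that prepares peptides for MHC class I rose with them: the immunoproteasome subunits Psmb8 (1.85) and Psmb9 (1.27), the peptide transporter Tap1 (1.09) and the transactivator Nlrc5 (1.06). Single epithelial and matrix genes rose as well, namely the intestinal cadherin Cdh17 (1.85), the keratin Krt18 (1.11), the laminin chain Lama3 (2.30-fold) and the thrombospondin Thbs2 (1.78).

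Mmp13 (ENSMUSG00000050578.10, chromosome 9, 7272514–7283331, plus strand) rose 15.9-fold from 7.60 ± 2.74 to 121 ± 20.6 CPM (log2 fold change 3.99 ± 0.21, adjusted p = 7.0e-08), and all 6 SIS ECM libraries lay above all 6 cells-alone libraries. So did all 6 for the aldehyde dehydrogenase Aldh3a1 (2.84 ± 0.34, adjusted p = 9.4e-05), the glutamate transporter Slc1a2 (2.84 ± 0.31, 4.6e-05), the scaffold kinase Cask (2.57), the guidance ligand Slit3 (2.10), the carboxylesterase Ces1f (2.13) and the prolactin-family hormone Prl2c2 (2.13). Oas2 (chromosome 5, 120730333–120749853, minus strand) rose by 1.68 ± 0.13 (adjusted p = 1.7e-06, 6 of 6 libraries). The lipid droplet protein Plin2 (0.70) and the stress factor Ddit3 (0.71) rose less. Falling genes included the adhesion molecule Nrcam (−1.15; 8.62 ± 0.39 to 3.86 ± 0.81 CPM), the peptide hormone receptor Calcrl (1.99-fold lower), the immediate early factor Egr3 (−0.94), the cyclooxygenase Ptgs2 (−0.86), the phosphatase Ptpn22 (−0.84), the quinone reductase Nqo1 (−1.39), the fatty acid elongase Elovl6 (−0.60), the YAP target Ankrd1 (−0.78) and the Wnt effector Lef1 (−0.47).

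**Figure D2:**
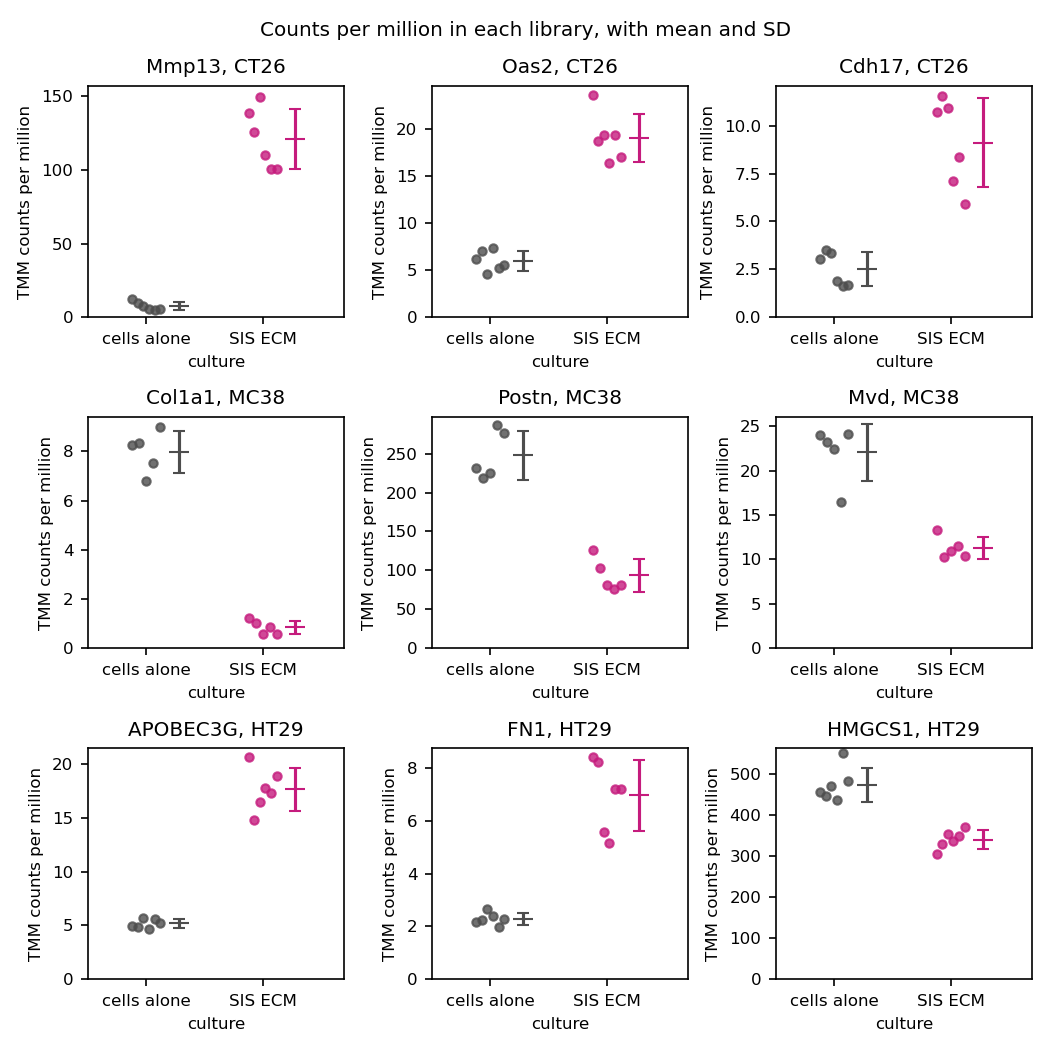
CPM of 3 genes per line in every library, with mean ± SD. Mmp13, Oas2 and Cdh17 rose in CT26, Col1a1, Postn and Mvd fell in MC38, and in HT29 APOBEC3G and FN1 rose while HMGCS1 fell.

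Of 25 interferon-stimulated genes tested in CT26, 22 rose and 1, Ifit2 (−0.47), fell (24 and 1 when adjusted over the list alone), with a median log2 fold change of 1.12 (1.07, 1.04; camera adjusted p = 6.5e-39). MHC class I genes rose in 7 of 12 (9 over the list alone, median 0.72 (0.70, 0.69), adjusted p = 6.8e-09). Matrix proteases and their inhibitors rose in 9 of 17 and fell in 1 (11 and 2 over the list alone, 0.44 (0.54, 0.26), adjusted p = 2.6e-07). Hypoxia genes rose through the growth factor Vegfa (0.45) and Ankrd37 (0.42), 2 of 19 (8 over the list alone, 0.34 (0.48, 0.17), adjusted p = 0.00080). With an estimated correlation these lists had adjusted p = 0.0524, 0.0524, 0.210 and 0.305, and interferon-stimulated genes passed when the block was added to it (0.0157).

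Smaller shifts in CT26 rested on few genes. Cell cycle genes shifted lower, with falls in the spindle motor Kif11 (−0.41) and the spindle assembly factor Tpx2 (−0.25), 2 of 30 (2 over the list alone, median −0.13 (−0.22, −0.06), adjusted p = 0.0010). Leaving out any of 5 of 12 libraries ended the call on Tpx2 (adjusted p up to 0.0702). Epithelial junction genes rose through Cdh17 and Krt18, 2 of 5 (2 over the list alone, 0.31 (0.28, 0.46), adjusted p = 0.0064). Glycolysis genes rose through the enolase Eno2 (0.70) and the kinase Pgk1 (0.36), 2 of 17 (2 over the list alone, 0.23 (0.39, 0.03), adjusted p = 0.0067), but not without SIS ECM library 2 (0.0732), and Pgk1 lost its call in 10 of 12 omissions (up to 0.101). Some lists did not pass in libraries 4 to 6 alone in CT26: glycolysis genes had adjusted p = 0.504 there, and cell cycle genes 0.113. With an estimated correlation these 3 lists had adjusted p = 0.305, 0.384 and 0.762.

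Other programs in CT26 did not pass: cholesterol synthesis (adjusted p = 0.0884), collagens and glycoproteins (0.121; 0.0157 with the number as a block, median 0.19 (0.39, −0.015)), immediate early (0.121), TGF-beta and YAP (0.172), mitochondrially encoded (0.181; 0.0010 with the block, median −0.23 (−0.57, 0.008)), NF-kB (0.310), unfolded protein (0.367), fatty acid (0.473), p53 (0.473), integrin (0.608), intestinal (0.608), NRF2 (0.793), stem cell and Wnt (0.824), fibroblast (0.877) and mesenchymal genes (0.883). Smooth muscle, leukocyte and endothelial markers had too few tested members (2, 2 and 0). With the replicate number as a block, 2281 genes changed in CT26 in place of 1135.

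MC38 spheroids with SIS ECM expressed less of their own matrix, less of the hypoxia and glycolysis programs and less of the cholesterol pathway. None of these lists passed with an estimated correlation (adjusted p = 0.143, 0.149, 0.0655 and 0.0655). With a term for the number ranges added, chosen after the data were seen, collagens (0.0415) and cholesterol synthesis genes (0.0022) passed. Hypoxia (0.176) and glycolysis genes (0.0624) did not. Matrix genes fell most: the collagens Col1a1 and Col12a1 (−1.20), the collagen-binding asporin Aspn (−2.41), periostin (Postn, −1.40) and tenascin C (Tnc, −1.05). Oxygen-regulated genes fell, among them the endoplasmic oxidase Ero1l (−1.12), the HIF hydroxylase Egln3 (−1.02), the glucose transporter Slc2a1 (−0.91) and the lactate exporter Slc16a3 (−0.59). Enzymes of the mevalonate part of sterol synthesis fell: Pmvk (−0.75), Mvd (−0.97) and Fdps (−0.57). Among the rising genes that the naming rule selected, the transcriptional repressor Bcl6b (2.12) changed most.

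Col1a1 (chromosome 11, 94936224–94953042, plus strand) fell 9.36-fold, from 7.98 ± 0.85 to 0.845 ± 0.272 CPM (log2 fold change −3.23 ± 0.18, adjusted p = 1.7e-06), with all 5 SIS ECM libraries below all 5 cells-alone libraries. Postn (chromosome 3, 54361109–54391037, plus strand) fell from 248 ± 31.1 to 93.7 ± 21.1 CPM (−1.40 ± 0.14, adjusted p = 8.5e-05, 5 of 5). All 5 libraries also lay lower for Aspn (−2.41 ± 0.21, adjusted p = 5.0e-05), the heme oxygenase Hmox1 (−1.67), the laminin receptor chain Itgb4 (−1.54), the basonuclin Bnc1 (−1.38), the early response gene Ier3 (−1.26) and the claudin Cldn1 (−1.08). Bcl6b (chromosome 11, 70224128–70229798) rose from 2.47 ± 0.29 to 10.8 ± 2.13 CPM (2.12 ± 0.15, adjusted p = 1.0e-05, 5 of 5). The sialyltransferase St3gal4 (0.99), the helicase and nucleic acid sensor Ddx41 (0.96), the G-protein regulator Rgs17 (0.95) and the interferon-inducible DNA sensor Ifi204 (0.92) rose as well. Mmp13 rose here too (1.46 ± 0.16, adjusted p = 1.7e-04) but stayed scarce, at 1.62 ± 0.30 and 4.42 ± 0.59 CPM.

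Collagens and matrix glycoproteins fell in 18 of 32 genes in MC38, with the thrombospondin Thbs1 (0.75) alone rising (25 and 2 over the list alone, median −0.54 (−0.47, −0.54), adjusted p = 1.6e-27). Cholesterol synthesis genes fell in 16 of 23 (19 over the list alone, −0.38 (−0.30, −0.35), adjusted p = 5.5e-18). Mvd (chromosome 8, 122433601–122443422, minus strand) went from 22.05 ± 3.22 to 11.3 ± 1.25 CPM (−0.97 ± 0.11, adjusted p = 3.2e-04, 5 of 5 libraries). Glycolysis genes fell in 12 of 18, with Gpi1 (−0.51) and Hk1 (−0.50) at its entry (16 over the list alone, −0.36 (−0.43, −0.26), adjusted p = 4.0e-13). Hypoxia genes fell in 10 of 20 (10 over the list alone, −0.38 (−0.85, −0.16), adjusted p = 3.1e-10). Fatty acid genes fell in 9 of 16, including the acetyl-CoA synthetase Acss2 (−0.88) and the desaturase Fads2 (−0.63) (11 over the list alone, −0.31 (−0.35, −0.25), adjusted p = 1.9e-08). With an estimated correlation these 5 lists had adjusted p = 0.143, 0.0655, 0.0655, 0.149 and 0.218.

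Further MC38 lists shifted less. Fibroblast markers fell through Col1a1 and the protease Fap (−0.73), 2 of 8 (3 over the list alone, −0.18 (−0.07, −0.21), adjusted p = 6.9e-08, and 0.0643 in libraries 1 to 3 alone). NRF2 genes fell in 4 of 18, Hmox1, the ferritin chain Ftl1 (−0.43), the transketolase Tkt (−0.38) and the transaldolase Taldo1 (−0.34, ended by each of the 10 omissions, up to 0.0922) (4 over the list alone, −0.16 (−0.09, −0.11), adjusted p = 0.0014). Integrins fell in 4 of 15, with Itgb4 and Itgb5 (−0.56) in front, while the collagen receptor chain Itga2 (0.58) rose (7 and 1 over the list alone, −0.16 (−0.01, −0.19), adjusted p = 0.0015, and 0.169 in libraries 1 to 3 alone). The call on Itga2 ended in 4 of 10 omissions, those of cells-alone libraries 1, 2 and 3 and of SIS ECM library 5 (up to 0.0645). MHC class I genes fell in 6 of 12, led by Tap2 (−0.45) and the immunoproteasome subunit Psmb10 (−0.43) (7 over the list alone, −0.27 (−0.18, −0.20), adjusted p = 0.0020, and 0.145 in libraries 1 to 3 alone). With an estimated correlation these 4 lists had adjusted p = 0.149, 0.143, 0.2197 and 0.188.

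Unfolded protein response genes in MC38 fell through the pseudokinase Trib3 (−0.89) and Atf4 (−0.19), 2 of 18 (2 over the list alone, −0.09 (−0.15, −0.12), adjusted p = 0.0150, and 0.218 with an estimated correlation), with Atf4 losing its call in 9 of 10 omissions (up to 0.0918) and with the block (0.0937). Interferon-stimulated genes rose in 3 of 26, Oasl2 (0.33), Irf9 (0.30) and the RNA sensor Ddx58 (0.23; 0.0653 with the block; ended by 6 of 10 omissions, up to 0.0780), and Irf1 (−0.30) fell (4 and 1 over the list alone, 0.12 (0.19, −0.01), adjusted p = 0.0257). Irf1 lost its call without cells-alone library 3 (0.0505). The list had adjusted p = 0.211 with the block, 0.502 with an estimated correlation, and 0.179 and 0.0717 without cells-alone library 2 or SIS ECM library 3. Mitochondrially encoded genes passed as a list (0.28 (0.58, −0.08), adjusted p = 0.0251) with 0 of 13 genes changed (0 over the list alone), and no longer with an estimated correlation (0.536) or in 4 of 10 omissions, those of cells-alone libraries 1, 2 and 3 and of SIS ECM library 4 (up to 0.0995).

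Lists that did not pass in MC38 were epithelial junction (adjusted p = 0.0833), TGF-beta and YAP (0.0882), NF-kB (0.114), immediate early (0.116), p53 (0.116), matrix protease (0.298; 0.0426 with the block), mesenchymal (0.405), intestinal (0.650), cell cycle (0.973), leukocyte (0.973) and stem cell and Wnt genes (0.973). Single members still fell, such as the early factor Junb (−0.98), the p53 targets Cdkn1a (−0.66) and Phlda3 (−0.41), the chemokine Ccl5 (−0.68) and the TGF-beta inhibitor Smad7 (−0.36). Smooth muscle and endothelial markers had 2 and 1 tested members. The number of genes changed by SIS ECM in MC38, 1206, depended on single libraries, going to 648, 626, 663 and 1948 without cells-alone library 1, 2, 3 or 4 and to 724 and 742 without SIS ECM library 4 or 6. With the replicate number as a block 1188 genes changed, and 881 of the 1206 still passed. That fit leaves out cells-alone library 2 and SIS ECM library 6, so calls lost in it may be owed to the missing libraries.

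HT29 cells with SIS ECM expressed more interferon-stimulated, MHC class I and matrix protease genes and less of the genes of cholesterol synthesis and intestinal differentiation. Antiviral genes rose: the cytidine deaminases APOBEC3G (1.77), APOBEC3C (1.43) and APOBEC3F (1.38), the membrane restriction factor IFITM1 (2.27-fold), the chemokine CXCL10 (1.26) and the effectors IFIT1 (0.80), RSAD2 (0.76) and MX2 (0.70). The neutrophil chemokines CXCL1 (1.15) and CXCL8 (1.07), the receptor kinase AXL (1.32), the matrix genes FN1 (1.60), COL6A1 (1.31) and TNC (0.66) and the plasminogen activators PLAT (2.20) and PLAU (0.94) rose. Genes of differentiated gut epithelium fell, among them the adhesion protein CEACAM5 (−0.80), the secreted lectin REG4 (−0.87), the cadherin CDH17 (−0.57), the regulator HNF4A (−0.42), the secretory chaperone AGR2 (−0.45), the mucin MUC13 (−0.40) and the lectin LGALS4 (−0.38). Sterol genes fell too, including the synthase HMGCS1 (−0.48), the sterol reductase HSD17B7 (−0.41) and the decarboxylase MVD (−0.38).

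APOBEC3G (ENSG00000239713.9) rose 3.42-fold from 5.18 ± 0.40 to 17.7 ± 2.02 CPM (log2 fold change 1.77 ± 0.08, adjusted p = 1.8e-10, 6 of 6 SIS ECM libraries above every cells-alone library). FN1 rose 3.04-fold from 2.28 ± 0.23 to 6.96 ± 1.35 CPM (1.60 ± 0.12, 3.2e-07, 6 of 6), and PLAT from 0.368 ± 0.111 to 1.73 ± 0.51 CPM (2.20 ± 0.23, 5.8e-06, 6 of 6). The host transcript MIR205HG rose by 1.71. The epithelial factor GRHL3 fell most among the genes named, from 11.8 ± 1.57 to 5.82 ± 0.56 CPM (−1.02 ± 0.09, 1.0e-06, 6 of 6), beside the sulfotransferase SULT1A4 (−0.90), the aldo-keto reductase AKR1B10 (−0.83), the zinc transporter SLC39A5 (−0.71), the metalloprotease MMP28 (−0.65) and the antisense transcript SSTR5-AS1 (−0.62). HMGCS1 went from 473 ± 41.2 to 340 ± 22.5 CPM (−0.48 ± 0.06, 2.8e-05, 6 of 6).

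Of 25 interferon-stimulated genes in HT29, 22 rose and 0 fell (24 over the list alone, median 0.53, adjusted p = 3.7e-48, and 0.0107 with an estimated correlation). Cholesterol synthesis genes fell in 20 of 24 (20; −0.26, 4.7e-22, 6.3e-05). In the same order, over the list alone, median, adjusted p and adjusted p with an estimated correlation, MHC class I genes rose in 10 of 13, with TAP1 (0.53), HLA-B (0.46) and PSMB9 (0.38) (11 and 1; 0.28, 2.7e-08, 0.0336). TGF-beta and YAP targets rose in 9 of 18, among them the latent TGF-beta binding protein LTBP2 (0.89) and the TGF-beta target PMEPA1 (0.58), while CCN2 (−0.58) fell (10 and 1; 0.16, 1.2e-07, 0.0130). Intestinal differentiation genes fell in 6 of 16 (9; −0.26, 1.8e-07, 0.0162). Proteases rose in 7 of 15, with PLAT, PLAU and the matrilysin MMP7 (0.57) (7; 0.21, 2.7e-07, 0.0312). NF-kB genes rose in 6 of 16, including the apoptosis inhibitor BIRC3 (0.56), while LCN2 (−0.29) fell (8 and 4; 0.23, 8.7e-05, 0.0107).

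The next HT29 lists passed at the preset correlation only. Unfolded protein response genes fell in 13 of 18, with CRELD2 (−0.43), the factor DDIT3 (−0.37) and HERPUD1 (−0.35) (16 over the list alone, median −0.24, adjusted p = 6.7e-11, and adjusted p = 0.0631 with an estimated correlation). Given in that order, mitochondrially encoded genes fell in 5 of 13, led by MT-ND4L (−0.48) and MT-ND4 (−0.37) (9; −0.22, 4.6e-06, 0.283). Their share of counts was lower in 4 of 6 SIS ECM libraries, while libraries 1 and 4 (6.61 and 6.89%) lay with or above cells alone (6.15 to 6.80%). NRF2 genes fell in 5 of 17 (5; −0.10, 3.0e-04, 0.126). Hypoxia genes rose in 6 of 19, with the lipase inhibitor ANGPTL4 (0.36) and the mitophagy receptor BNIP3L (0.31) (7; 0.19, 3.2e-04, 0.376). Stem cell and Wnt genes rose in 7 of 16, including TNFRSF19 (0.86), the stem cell factor ASCL2 (0.44), the crypt receptor EPHB2 (0.39) and SOX9 (0.37), while LGR4 (−0.23) and PROM1 (−0.13) fell (9 and 2; 0.26, 4.4e-04, 0.256). Collagens and glycoproteins rose in 5 of 21 and the basement membrane chain COL4A2 (−0.40) fell (7 and 1; 0.13, 4.8e-04, 0.283). Integrins rose in 5 of 15, with ITGB6 (0.35) and ITGAV (0.31), which pair to activate TGF-beta (8 and 1; 0.13, 0.0011, 0.145). Glycolysis genes rose in 5 of 18, with the kinase PKM (0.25) and SLC16A3 (0.24), while ALDOC (−0.22; ended by 8 of 12 omissions, up to 0.0851) fell (5 and 1; 0.11, 0.0035, 0.406).

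Epithelial junction (adjusted p = 0.140), fatty acid (0.151), immediate early (0.495), leukocyte (0.495), mesenchymal (0.495), p53 (0.499), smooth muscle (0.572) and cell cycle genes (0.709) did not pass in HT29, though the acetyl-CoA synthetase ACSS2 (−0.54) fell here as in MC38. Fibroblast and endothelial markers had 1 and 2 tested members. The number of lists that passed in a line was not beyond other splits of its libraries. Those splits passed a median of 6 lists in CT26, 6 in MC38 and 8 in HT29. Passing at the preset correlation is therefore weak support for a list by itself.

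**Figure D3:**
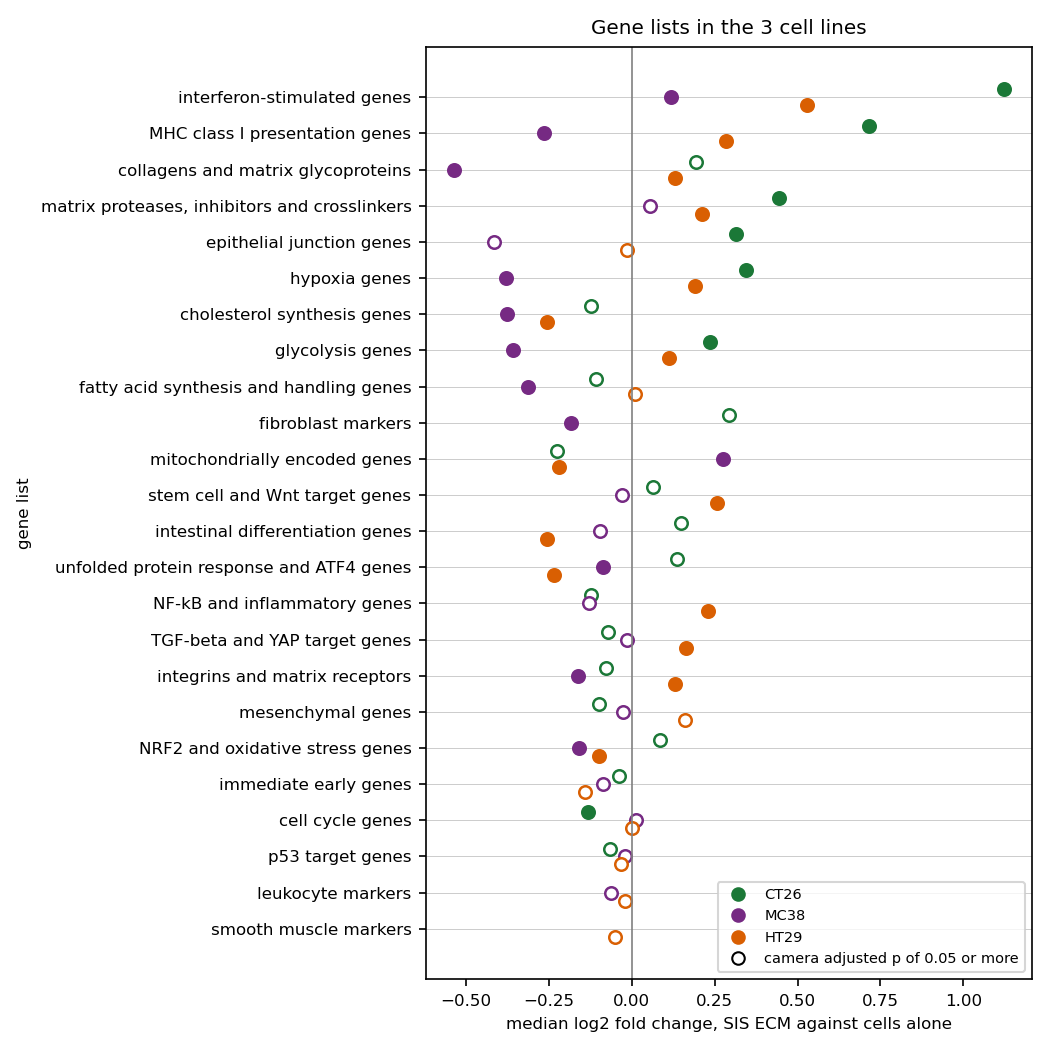
Median log2 fold change of each gene list in each line, filled where the camera adjusted p is below 0.05. Interferon-stimulated genes rose most in CT26 and collagens fell most in MC38.

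The mouse lines differed in their answer to SIS ECM in several programs. Interferon-stimulated genes rose in 22 of 25 in CT26 and in 3 of 26 in MC38, MHC class I genes rose in CT26 (7 of 12) and fell in MC38 (6 of 12), and hypoxia and glycolysis genes fell in MC38 but not in CT26. None of these lists passed within a line when the correlation was estimated (adjusted p = 0.0524, 0.0524, 0.305 and 0.762 in CT26 and 0.502, 0.188, 0.149 and 0.0655 in MC38). Collagens, whose genes fell in MC38, did not pass in CT26. The response differed in 1165 of 14080 genes (8.27%; 404 more positive in MC38, 761 less). The GABA-catabolic dehydrogenase Aldh5a1 (chromosome 13, 24907579–24937661; difference −4.35 ± 0.48, adjusted p = 2.8e-06) went from 2 to 43 counts in CT26 (ratio 21.4, 95% interval 5.58 to 182) and from 10.3 to 8.14 CPM in MC38. The angiopoietin gene Angpt1 (−4.55, 0.0117) went from 0 to 13 counts in CT26, 4.31-fold over a floor of 3 counts. It was seen in 6 of 6 SIS ECM libraries, though reads carried over from MC38 libraries were not excluded for it. These ratios pool counts over libraries, and the interval of Aldh5a1 leaves out the spread between libraries. The zinc finger gene Zfp704 (chromosome 3, 9427020–9610085; 3.63 ± 0.61, 7.0e-04) went from 0.818 to 0.0634 CPM in CT26 and from 64.1 to 70.8 CPM in MC38, and Bcl6b (1.65 ± 0.14, 4.2e-08) rose in MC38 above its change in CT26. Zfp704 was too scarce to be tested within CT26 (83 and 7 counts), and carried-over MC38 reads were not tested for it.

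As lists, with the number of genes differing, over the list alone, the median difference (libraries 1 to 3, libraries 4 to 6), adjusted p and adjusted p with an estimated correlation, interferon-stimulated genes were less positive in MC38 in 19 of 26 and more in 1 (24 and 1; −0.99 (−0.96, −1.03), 1.0e-23, 0.0481). MHC class I genes differed in 8 of 12 (11; −0.88 (−0.95, −0.80), 1.6e-13, 0.0085) and hypoxia genes in 10 of 20 (15; −0.71 (−1.29, −0.37), 2.9e-10, 0.0481). These 3 lists passed under either correlation, but with an estimated correlation hypoxia genes no longer did once the block (adjusted p = 0.185) or a term for the number ranges (0.0785) was added. Collagens differed in 14 of 34 (18; −0.89 (−0.99, −0.56), 1.9e-11, 0.253), glycolysis genes in 10 of 19 (16; −0.67 (−1.003, −0.26), 6.8e-10, 0.150) and proteases, with Mmp13 (−2.54), Mmp3 (−1.74) and Mmp10 (−1.69), in 6 of 21 (9; −0.59 (−0.54, −0.22), 6.2e-05, 0.150).

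**Figure D4:**
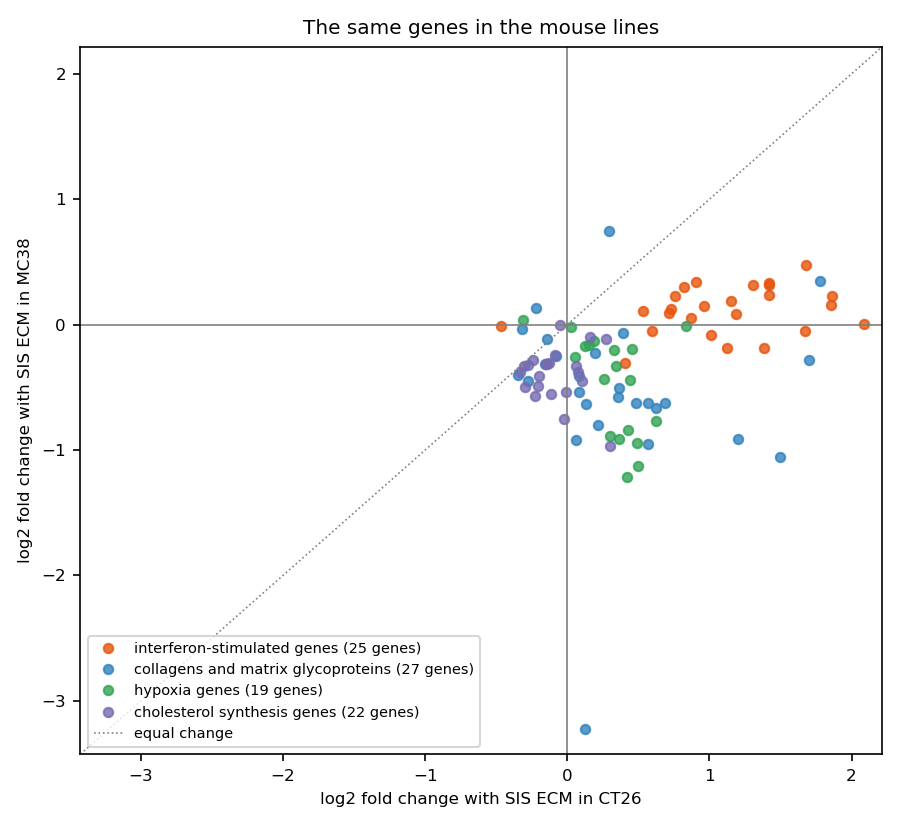
Log2 fold change with SIS ECM in CT26 (x) and MC38 (y) for interferon-stimulated, collagen, hypoxia and cholesterol genes, with equal change dotted. Most genes lie below the line of equal change.

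Weaker list differences between MC38 and CT26 follow in the same order. Cholesterol genes differed in 5 of 23 (6; −0.27 (−0.15, −0.37), 7.1e-04, 0.383; 0.522 in libraries 1 to 3 alone), fibroblast markers in 2 of 9, Col1a1 (−3.36) and the proteoglycan Dcn (−0.74) (4 lower and 1 higher; −0.47 (−0.44, −0.25), 0.0036, 0.246; 0.142 in libraries 1 to 3 alone), and cell cycle genes in 1 of 30, Kif11 (0.48) (0.17 (0.30, −0.01), 0.0045, 0.303). Mitochondrially encoded genes differed in 0 of 13 (0.37 (1.22, −0.16), 0.0090, 0.651). Fatty acid genes (1 more and 2 less of 16; −0.32 (−0.28, −0.23), 0.0218, 0.651) lost their call in 6 of 22 omissions (up to 0.0549). Unfolded protein response genes (Trib3 −1.25 and Ddit3 −1.03, 2 of 18; 3; −0.23 (−0.38, −0.06), 0.0330, 0.423) lost it in 5 (up to 0.0812). NRF2 genes (5 less and 1 more of 18; 6 and 1; −0.14 (−0.19, −0.03), 0.0339, 0.421; 0.0622 with the block) lost it in 7 (up to 0.0787). Within libraries 1 to 3 alone the fatty acid list did not pass, and within libraries 4 to 6 alone the unfolded protein response list did not. Integrin (0.141), epithelial junction (0.501), intestinal (0.599), TGF-beta and YAP (0.599), NF-kB (0.621), p53 (0.649), stem cell and Wnt (0.734), mesenchymal (0.838) and immediate early genes (0.887) did not pass.

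TGF-beta and YAP targets and NF-kB genes answered more positively in HT29 than in the mouse lines. Only these lists passed under either correlation. The receptor kinase AXL differed by 1.53, LTBP2 by 0.85 and PMEPA1 by 0.70. Among NF-kB genes the chemokine CXCL1 differed by 1.32, the NF-kB inhibitor TNFAIP3 by 0.88, the cyclooxygenase PTGS2 by 0.77 and the growth factor CSF1 by 0.69. Over 12272 symbol-matched genes, 668 differed (317 more positive in HT29, 351 less), and 1023 with the block. TGF-beta and YAP targets were more positive in HT29 in 7 of 20 (10 and 1 over the list alone, median 0.21, adjusted p = 9.1e-07, and adjusted p = 0.0025 with an estimated correlation), and NF-kB genes in 4 of 18 (0.26, 0.0072, 0.0464). Neither list passed with an estimated correlation and the block (both adjusted p = 0.0578). The other lists that passed did so at the preset correlation only: unfolded protein response genes, less positive in 4 of 17, with the chaperones and folding factors CRELD2 (−0.53), MANF (−0.35) and PDIA4 (−0.21) and the regulator XBP1 (−0.30) (8 over the list alone, −0.24, 2.9e-04, 0.293), hypoxia genes in 1 of 19, BNIP3L (0.27) (0.19, 0.0056, 0.601), collagens in 2 of 36, COL1A1 (1.66) and FN1 (1.61) (0.27, 0.0072, 0.773) and glycolysis genes in 0 of 17 (0.14, 0.0072, 0.699). A more positive difference can come from falls in a mouse line, and Col1a1 fell strongly in MC38. Of the collagen list, only 21 genes had enough counts to be tested in HT29 alone. Fatty acid genes (2 of 14; 3; 0.15, 0.0441, 0.773; 0.184 with the block) lost their call in 17 of 34 omissions (up to 0.0790) and integrins (1 of 16; 2 and 2; 0.14, 0.0441, 0.699) in 16 (up to 0.0810).

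Interferon-stimulated genes (adjusted p = 0.338) did not pass between HT29 and the mean of the mouse lines, which averages a strong and a weak response. Cell cycle (0.160), mitochondrially encoded (0.160; 0.0097 with the block), MHC class I (0.179), smooth muscle (0.179), NRF2 (0.390), leukocyte (0.456), fibroblast (0.624), stem cell and Wnt (0.624), endothelial (0.706), immediate early (0.706), intestinal (0.706), p53 (0.706), cholesterol (0.778), protease (0.778), mesenchymal (0.778) and epithelial junction genes (0.939) did not pass either. Symbol matching leaves out genes named differently in the species.

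A small shared response crossed all lines. The nucleic acid sensor ZBP1 rose by 1.67, 0.42 and 0.68 in CT26, MC38 and HT29, the interferon-induced PARP14 by 0.96, 0.29 and 0.41 and the membrane protein CMTM3 by 0.59, 0.56 and 0.68. Of 8827 genes tested in every line, 19 changed in one direction in all (15 higher, 4 lower), where independent lists give 1.33 and 0.904. The cholesterol exporter ABCA1 (1.04, 0.60, 0.66), the chaperone RTP4 (1.45, 0.46, 0.51), the thrombin receptor F2R (0.61, 0.46, 0.34) and FAM102A (1.54, 0.99, 0.24) rose, and TMCC3 (−0.38, −0.53, −0.42), the sterol enzyme NSDHL (−0.31, −0.33, −0.31), the phosphatase ENTPD5 (−0.39, −0.37, −0.21) and the water channel AQP1 (−0.34, −0.63, −0.19) fell. Calls ended in omissions for Abca1 in MC38 (8 of 10, up to 0.0977), Rtp4 in MC38 (6, 0.0990), F2r in CT26 (6 of 12, 0.0836), FAM102A in HT29 (9, 0.0923), Tmcc3 in CT26 (7, 0.0763), Nsdhl in CT26 (3, 0.0552) and MC38 (1, 0.0552), Entpd5 in CT26 (9, 0.0819) and MC38 (6, 0.0817) and AQP1 in HT29 (2, 0.0537).

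Pairs of lines shared rising genes beyond independence: 49 in CT26 and MC38 (15.3 under independence, Fisher adjusted p = 1.0e-12), 86 in CT26 and HT29 (40.3, 2.1e-11) and 43 in MC38 and HT29 (25.4, 9.4e-04). Falling genes were shared by 14 in CT26 and MC38 (15.7, 0.791), 25 in CT26 and HT29 (16.5, 0.0453) and 49 in MC38 and HT29 (27.9, 2.3e-04). Fisher's test takes genes as independent of each other, but genes of one program change together. The estimated correlation was 0.60 for interferon-stimulated genes in CT26, so these p-values are likely too small. Genes with opposite changes numbered 37 (34.8 under independence), 64 (51.6) and 83 (58.95), above independence as well in the pairs with HT29. Across all genes the log2 fold changes of the lines did not follow each other (Pearson r = −0.09, 0.09 and −0.01).

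The authors' deposited table held 1551 genes below an adjusted p of 0.05 in CT26 (785 higher, 766 lower), 1090 in MC38 (536, 554) and 2166 in HT29 (1120, 1046). Of all genes in both, 88.8, 95.8 and 96.0% had the same sign in the authors' deposited table and here. The log2 fold changes in the authors' deposited table correlated with those found here at 0.953, 0.953 and 0.965. Genes called in both, 944, 789 and 1910, all had one sign in the authors' deposited table and here. Both start from the same libraries, so this compares methods and adds no new samples.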

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

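The test on markers of other cell types, the test on MC38-restricted transcripts and the test on transcripts near 0 were chosen, and the bounds of the marker and MC38 tests later tightened, only after the results they bear on were seen. The other splits of the libraries were planned.

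Other splits of the same libraries gave fewer changed genes than the cultures did, with some exceptions. Counting the true split itself, as many genes were called in 1 of 100 splits in CT26 (1135, next 1), 2 of 100 in MC38 (1206), 1 of 100 in HT29 (2058, next 1640), 2 of 80 for the difference between MC38 and CT26 (1165), 1 of 40 for HT29 against the mouse lines (668, next 351) and 1 of 100 for the genes shared by all lines (19, next 0). The other MC38 split that reached the count, with 3978 genes, was the division into number ranges itself. That for the difference, with 1316, held the ranges unequally, but other splits that held them as unequally called 0 or 8 genes. The 1640 genes in HT29 came from a split that put SIS ECM libraries 1 and 4 with cells-alone libraries. Other splits that placed these libraries so called 891, 6 or 0 genes, so their placing alone does not account for the count. In splits that part every pair of one number the next count was 0, over 32 splits in CT26 and 16 in MC38. Most other splits called no gene at all within a line (98 in CT26, 97 in MC38 and 92 in HT29). Such splits cannot share genes across lines, so the next count of 0 for shared genes was nearly fixed and says nothing about a shared response.

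The number of gene lists passed was not beyond such splits. As many lists as in the true split passed in 41 of 100 splits in CT26 (7 lists, up to 15 elsewhere), 9 of 100 in MC38 (12, up to 13), 8 of 100 in HT29 (15, up to 16), 4 of 80 for MC38 against CT26 (13, up to 15) and 8 of 40 for HT29 against the mouse lines (8, up to 12).

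The interferon response of CT26 was weighed against 3 other sources: the number ranges, scaling and RNA from other cells, which stayed open. The lower of its medians within the number ranges was 1.04, so the response was present in each range. Under other scaling the lower median was 1.113. The other scalings moved the genes of CT26 by a median of only −0.011 and 0.012 log2, so the scaling test could hardly have come out otherwise. Of 11 tested markers of other cell types, 1 reached the list's median, the macrophage marker Cd68 (1.58, adjusted p = 0.0666), while Mylk (0.92), Dcn (0.65) and Cd14 (0.53) rose and Pdpn (−0.47) fell. CT26 cells alone already express most of these markers, which would hide a small share of other RNA, so such RNA was not excluded.

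The hypoxia genes, lower with SIS ECM in MC38 than in CT26, kept a median difference of −0.369 in the weaker number range and −0.7014 under the weaker other scaling. The difference was thus present in both ranges, though its size depended on the range. The other scalings moved the genes of this comparison by a median of only 0.005 and −0.020 log2, so the scaling test could hardly have come out otherwise.

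Transcripts near 0 in CT26 cells alone that appear with SIS ECM included Col5a3, Aldh5a1, Angpt1 and Ppp1r9a, among 5 tested. Reads of MC38 libraries could have entered CT26 libraries sequenced in one pool. Transcripts restricted to MC38 (154, with 436 counts) reached 0.0348% of their MC38 level together in CT26 with SIS ECM and up to 1.72% singly, and 24 of them reached the 0.0823% of Col5a3. Aldh5a1 (3.95%, lower limit 2.86%) lay above all of them, whereas the other 4 genes, at up to 0.828%, did not, so carry-over stays open for these. Within both number ranges, 2 of 5 (Aldh5a1 and Angpt1) rose beyond counting error, and for the others the ranges might be the source.

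The gene differences between MC38 and CT26 were 3.628 for Zfp704, 2.975 for Klk10, 1.699 for Gpr149, 1.65 for Bcl6b, 1.268 for Nipal1, −4.284 for Col5a3, −4.355 for Aldh5a1, −4.547 for Angpt1 and −4.865 for Ppp1r9a. Calls ended when single libraries of 22 were left out for the kallikrein gene Klk10 (4, adjusted p up to 0.123), Gpr149 (15, 0.134), Col5a3 (12, 0.161) and Ppp1r9a (9, 0.0713). Klk10 rested on 1 and 9 counts in MC38 (ratio 9.20, 1.27 to 403), Zfp704 on 83 and 7 counts in CT26 and Gpr149 on 23 and 8. Carry-over was not tested for these genes. In CT26, Col5a3 had a ratio of 12.9 (1.94 to 550) and Ppp1r9a was 6.97-fold higher over a floor of 3 counts. These ratios pool counts, and their intervals leave out the spread between libraries.

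The median differences of lists between MC38 and CT26 were −0.9899 for interferon-stimulated, −0.8821 for MHC class I, −0.8941 for collagen, −0.7077 for hypoxia, −0.6652 for glycolysis, −0.5853 for protease, −0.2663 for cholesterol, −0.4688 for fibroblast, 0.1689 for cell cycle, 0.3721 for mitochondrially encoded, −0.319 for fatty acid, −0.2278 for unfolded protein and −0.1379 for NRF2 genes. Those between HT29 and the mouse lines were 0.2104 for TGF-beta and YAP targets, −0.2412 for unfolded protein, 0.19 for hypoxia, 0.2714 for collagen, 0.1404 for glycolysis, 0.2556 for NF-kB, 0.1464 for fatty acid and 0.1378 for integrin genes.

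Single libraries stood apart from their group by Dixon's ratio in 17 of 326 sets, where 16.3 fall by chance. In CT26 these were glycolysis genes in cells-alone library 3 (ratio 0.6479), Rtp4 in SIS ECM library 1 (0.6847; 17.8 against 12.2 to 14.0 CPM), Aqp1 in SIS ECM library 3 (0.6875) and Nrcam in cells-alone library 4 (0.7355). In MC38 they were intestinal genes in cells-alone library 5 (0.7786), interferon-stimulated genes in SIS ECM library 1 (0.7495), MHC class I (0.7664) and immediate early genes (0.8175) in cells-alone library 4 and Fam102a in cells-alone library 1 (0.7197). In HT29 they were collagens in cells-alone library 5 (0.7994) and SIS ECM library 4 (0.6917), TGF-beta and YAP targets in cells-alone library 5 (0.7283), MIR205HG in SIS ECM library 2 (0.842; 14.7 against 11.4 to 11.9 CPM), ABCA1 in cells-alone library 3 (0.7323), F2R in SIS ECM library 1 (0.7374), SSTR5-AS1 in SIS ECM library 4 (0.6412) and SULT1A4 in SIS ECM library 5 (0.6342).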

How the results depend on the processing

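The term for number ranges, each range alone and HT29 without SIS ECM libraries 1 and 4 were chosen only after the results were seen. The remaining alternatives were planned.

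Counts of changed genes moved with the treatment of the number ranges. CT26 had 1135 genes, 2281 with the number as a block, 1763 with both mouse lines in one fit, 3545 with a term for the ranges, 2484 in libraries 1 to 3, 2333 in libraries 4 to 6 and 222 at 2-fold or more. MC38 had 1206, with 538, 3246, 5287, 2318 and 77 for the joint fit, the term, libraries 1 to 3, libraries 4 to 6 and 2-fold, and 626 to 1948 when single libraries were left out. The difference between MC38 and CT26 had 1165 genes, 3740 with the term, 4112 in libraries 1 to 3 and 2001 in libraries 4 to 6. HT29 against the mouse lines had 668, 1023 with the block and 1699 with the term.

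HT29 had 2058 genes, 53 at 2-fold or more, 1880 with the number as a block and 3617 without SIS ECM libraries 1 and 4. That last fit ended a call in HT29: glycolysis genes no longer passed (0.0567). The shared genes numbered 19, with 33 by DESeq2, 60 with the term, 60 in libraries 1 to 3 and 43 in libraries 4 to 6.

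With an estimated correlation between genes, 0 lists passed in CT26, 0 in MC38, 7 in HT29, 3 for MC38 against CT26 and 2 for HT29 against the mouse lines. With the term for the ranges added, 4 passed in CT26, 4 in MC38, 2 for MC38 against CT26 and 2 for HT29 against the mouse lines. Those in CT26 were interferon-stimulated (adjusted p = 0.0038), MHC class I (0.0247), epithelial junction (0.0247) and protease genes (0.0282). Those in MC38 were cholesterol synthesis (0.0022), collagen (0.0415), fatty acid (0.0415) and NRF2 genes (0.0444). Without a filter on low counts a list was lost in CT26: epithelial junction genes had adjusted p = 0.104. Integrins between HT29 and the mouse lines were lost without the filter (0.0521) and with library totals alone (0.0639), and unfolded protein response genes between MC38 and CT26 were lost with library totals alone. Interferon-stimulated genes in CT26 went from adjusted p = 0.0524 to 0.0157 with the block and 0.0038 with the term. Among lists that had passed, 4 medians changed sign in libraries 4 to 6 alone: −0.0077155 for interferon-stimulated and −0.081468 for mitochondrially encoded genes in MC38, and −0.011987 for cell cycle and −0.16243 for mitochondrially encoded genes between MC38 and CT26. No named gene that had passed changed sign. Of these genes, 48 of 65 in CT26, 44 of 73 in MC38, 85 of 97 in HT29 and 4 of 10 between MC38 and CT26 kept their call under every alternative in which they were tested. The 2-fold minimum was not applied to named genes, and genes that a filter removed were not counted as lost.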

Other observations

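The LXR test was chosen only after the fall of sterol genes was seen.

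The authors' deposited table of Hallmark sets gives a view of wider programs. In CT26 the authors' deposited table held 23 of 50 sets below an adjusted p of 0.05 (17 higher, 6 lower; smallest 0.0024), led by interferon alpha (enrichment score 3.03), interferon gamma (2.94) and hypoxia (2.12), with E2F targets (−2.42), the G2M checkpoint (−2.35) and MYC targets (−1.92) lower. In MC38 the authors' deposited table held 29 sets, all lower (smallest 0.0011), with hypoxia (−2.68), myogenesis (−2.54), epithelial-mesenchymal transition (−2.50), cholesterol homeostasis (−2.38), MTORC1 signalling (−2.29) and glycolysis (−2.22) in front. In HT29 the authors' deposited table held 34 sets (23 higher, 11 lower; smallest 0.0014), with interferon alpha (3.21), interferon gamma (3.13), the inflammatory response (2.38), epithelial-mesenchymal transition (2.35) and TGF-beta signalling (2.12) higher and cholesterol homeostasis (−2.60), oxidative phosphorylation (−2.36) and the unfolded protein response (−1.95) lower.

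Sterol genes fell in MC38 and HT29, while the exporter ABCA1 rose in both. More sterol in the cells could produce both changes, the rise of ABCA1 through LXR. The LXR targets bear only on that rise. Other LXR targets did not follow this in MC38, where their median was −0.2686 over 3 tested and the acyltransferase Lpcat3 (−0.34) fell. In HT29 the sterol exporter ABCG1 (0.42) and the phospholipid transfer protein PLTP (0.29) rose, 2 of 6 tested (median 0.13). The bound set against LXR, a median at or below 0 in 1 of the lines, was thus met in MC38. With 3 targets tested there and 1 of them changed, the test cannot exclude LXR. ABCA1 rose in CT26 as well (1.04), where cholesterol synthesis genes did not pass camera (adjusted p = 0.0884). Its call in MC38 ended in 8 of 10 omissions.

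Mitochondrially encoded transcripts made up 6.15 to 6.80% of counts in HT29 cells alone. SIS ECM libraries 1 and 4 lay with these (6.61 and 6.89%), and the other 4 SIS ECM libraries held 5.33 to 5.80%. Over all libraries the shares were 6.51 and 5.91% (exact permutation p = 0.0714, adjusted p = 0.286). CT26 libraries with SIS ECM held more detected genes, 17176 ± 319 against 16752 ± 156 (exact permutation p = 0.0043, adjusted p = 0.0519).

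Among leukocyte markers in HT29, the lysosomal protein LAPTM5 (0.64) and the MHC class II chaperone CD74 (0.52) rose and CD68 (−0.18) fell. CD74 can be induced in epithelial cells by interferon gamma.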
